A study of Homo sapiens with 12 samples.

How the data were processed

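HEK293 cells were fixed, their chromatin was sonicated, and G-quadruplexes were precipitated with the BG4 antibody before tagmentation and sequencing, per the labels' protocols. The 12 samples are 3 biological replicates, each with 3 technical ChIP libraries and 1 input made without the antibody step. Groups and technical numbers were taken from the sample titles. The inputs were not analysed here. The titles do not say whether the biological replicates came from separate cultures on separate days, and the p-values between them measure only the spread between technical libraries.

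The deposited coverage values are raw read counts per window of 400 bp, 200 bp to each side of an annotated TSS (GENCODE release 28, hg38), without scaling for depth or input. The deposited peak lists give chromosome, start and end, 1 list per biological replicate over its technical libraries, with no score or p per peak. The submitters' processing notes name cutadapt, BWA, Picard, MACS2 and bedtools and the build hg38, without versions, roles or thresholds. The authors' peak threshold, the rule that joined the technical libraries, and whether marked duplicates were left out of the counts are not given in the sources used here. Duplicate removal would cap the reads of the densest windows.

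The windows carry Ensembl IDs and no gene names. Names were therefore assigned by position from a RefSeq gene table of the same assembly (GRCh38): a window took the gene whose 5′ end lay within 200 bp of its TSS, protein-coding genes first and then the nearest, and 443 genes reached at both ends were dropped. This named 35638 windows, 13762 of them for protein-coding genes, or 68.6% of the 20056 in the table. With the TSSs shifted by 10000 bp, 312 windows received a protein-coding name, 2.27% of the real number. At shared promoters a name can be that of a neighbouring gene. Windows lie at the outermost annotated TSS and can miss the main promoter of a gene. Of all windows, 12.2% overlap another and share its reads.

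Depth ranged from 372030 to 846114 reads in windows per library, with 5.15 to 9.97% of windows empty. This total is not the library's full depth. CPM is scaled to the reads in windows. Values were averaged over the 3 technical libraries and are given as mean ± SD over 3 biological replicates. Shares have 95% Wilson intervals, which cover counting error only.

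Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 were used. Windows were compared between biological replicates with edgeR's quasi-likelihood test on the counts (TMM, filterByExpr, robust fit, Benjamini-Hochberg at 0.05), a 2 df test over the 3 replicates and 3 contrasts from the same fit. The common dispersion was 0.0011. The fit was tested on simulated data with 200 changed windows among 17499: it called 19.4% of 1.5-fold, 62.7% of 2-fold and 84.8% of 3-fold changes, with 10 false calls. Library correlations used log2 CPM with a prior of 1 and an exact permutation test over 280 splits.

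A peak was shared when peaks of both other replicates overlapped it by 1 bp or more. Shared peaks were merged into consensus regions, and a window had a consensus peak when all 3 lists had a peak in it. Random expectations came from 1000 placements within the chromosome, up to its last annotated base. Location classes used TSSs and RefSeq gene bodies, since exons were not used here. Gene lists were fixed before the data were examined: 22 lists were tested with Fisher's exact test against other protein-coding genes, and their read density (log2 CPM, prior 0.5) against 10000 random lists. A list of mitochondrially encoded genes was only described. The list test was tested on simulated data for lists of 50 genes among 13762: it found 97% of lists drawn with odds raised 3-fold and passed 6% of unchanged lists at an unadjusted p under 0.05. Smaller lists and lowered odds were not simulated, so the 97% does not cover them.

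Named genes followed a rule set before the data were examined: every textbook G-quadruplex promoter with a window, the 20 protein-coding genes with the highest lowest-of-9 CPM in a window with a consensus peak, the 5 largest changes each way per contrast (none passed), and up to 2 members per list with and 2 without a consensus peak, by mean CPM. Some genes that this rule named are not reported here, and they still count in the lists they belong to. Other names were chosen after their values were seen.

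Alternatives tried were other size factors, no filter, DESeq2, the technical number as a block, other priors, overlap rules, peak sets and backgrounds, and leaving out each library or biological replicate. Chosen after seeing the data were the settings without mitochondrial windows, the thinning to the same total of reads in windows, naming within 1 kb, and the position relative to the TSS. The planned corrections for GC content and the search for G-quadruplex motifs need a genome sequence, which was not used here.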

Results

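G-quadruplexes are stacked structures that guanine-rich DNA can fold into. They were profiled in HEK293, an established human embryonic kidney cell line, by chromatin immunoprecipitation with BG4, an antibody fragment that binds them. The series holds 3 biological replicates (BioRep1, BioRep2 and BioRep3), each with 3 technical ChIP libraries and 1 input. The values used here were read counts of the 9 ChIP libraries in windows of 400 bp, each centred on an annotated transcription start site (TSS), and 1 peak list per biological replicate. The inputs were not used here, so no level was compared with a library made without the antibody. The windows held between 372030 and 846114 reads per library, and 1562658, 2061045 and 1931653 reads in all for BioRep1, BioRep2 and BioRep3. The design has a single condition. The questions it poses are therefore where the BG4 signal lay, which promoters and gene groups carried it, and how closely the replicates matched.

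Peaks recurred at the same places in all 3 biological replicates. BioRep1 had 7931 peaks, BioRep2 11665 and BioRep3 13049, with median lengths of 124, 149 and 169 bp. The shortest peak in each list was 1 bp long, and 1035, 1155 and 1154 peaks were under 50 bp. Gaps between neighbouring peaks were under 100 bp in 975, 1367 and 1329 cases, so some peaks may be pieces of a longer one. Of the BioRep1 peaks, 85.6% (95% Wilson interval 84.8 to 86.4%) were overlapped by a peak in both other replicates. The corresponding shares were 53.8% (52.9 to 54.7%) for BioRep2 and 47.2% (46.4 to 48.1%) for BioRep3. Peaks of the same lengths placed at random within their chromosomes gave mean shares of 0.158%, 0.101% and 0.121%, and no placement among 1000 passed 0.252%. The shares differed mainly with the lengths of the lists: 92.6% of the BioRep1 peaks were overlapped in BioRep3, and 50.0% of the BioRep3 peaks in BioRep1. The value depended on what counted as shared, since an overlap of 50% of both peaks gave a mean of 30.9% in place of 62.2%. The intervals cover counting error only.

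**Figure D1:**
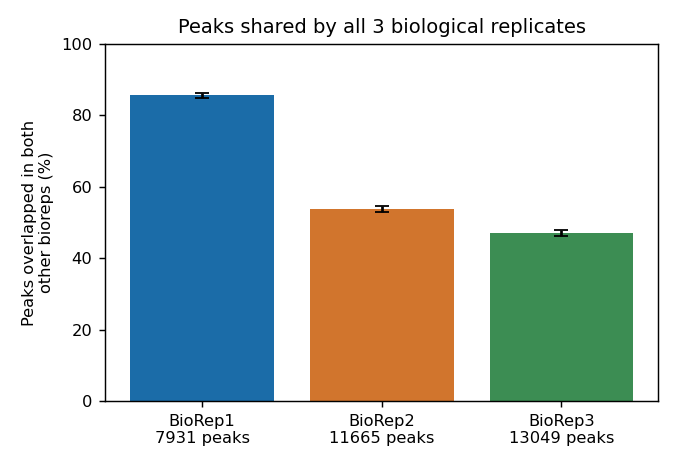
Share of each biological replicate's peaks (bars, %) that a peak in both other replicates overlapped by 1 bp or more, with 95% Wilson intervals. The share was 85.6% for the 7931 peaks of BioRep1, 53.8% for the 11665 of BioRep2 and 47.2% for the 13049 of BioRep3.

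Merging the peaks that all 3 replicates shared gave 6081 consensus regions with a median length of 324 bp, and most of them lay at TSSs. Of these regions, 70.6% (69.4 to 71.7%) touched a TSS window, against a mean of 1.84% for regions placed at random and a highest value of 2.35% in 1000 placements. The enrichment over random placement was 38.4-fold. By their midpoints, 81.4% (80.4 to 82.3%) of the regions lay within 1 kb of a TSS. A further 12.3% (11.5 to 13.2%) lay in a RefSeq gene farther from any TSS, where random placement gave 52.5%, and 6.28% (5.70 to 6.92%) lay outside both, where it gave 43.0%. Chromosome 19 had the densest regions among the nuclear chromosomes, with 9.76 per Mb. Chromosome 17 followed with 5.05 per Mb, and chromosome 18 had 0.798 per Mb. By promoters the order differed, with a consensus peak at 24.4% of the protein-coding windows of chromosome 19 and 34.2% of those of chromosome 22. The mitochondrial genome held 18 regions, and all 9 of its protein-coding windows that received a name had a consensus peak.

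A consensus peak lay in 5218 TSS windows (8.94%, 8.71 to 9.17%), while 49153 windows had no peak in any list, and the share differed between gene classes. Among protein-coding genes it was 25.4% (24.7 to 26.1%), or 3492 of 13762 windows. Among long non-coding RNA genes 494 of 5299 windows had one (9.32%, 8.57 to 10.1%), and among pseudogenes 6 of 12648 (0.0474%, 0.0217 to 0.103%). MicroRNA genes had one in 17 of 1689 windows (1.01%, 0.629 to 1.61%) and small nucleolar RNA genes in 2 of 749 (0.267%, 0.0733 to 0.968%). If the 3 lists had been independent, 560 protein-coding windows would have had a peak in all of them. Keeping only peaks wider than the median of their list lowered the count of windows from 5218 to 3073.

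The midpoints of regions near protein-coding promoters lay mostly just upstream of the TSS, a comparison added after the data were seen. Consensus regions had a median length of 324 bp, so a region with its midpoint upstream can still span the TSS. Of 3585 consensus regions with a protein-coding TSS within 1 kb of their midpoint, 2447 had the midpoint upstream of the nearest one (68.3%, 66.7 to 69.8%). The median midpoint lay at -43 bp, with quartiles at -105 and 19 bp. The bin from -100 bp to the TSS held 1500 regions and the bin from the TSS to 100 bp downstream held 698. Next to these, the bin from -200 to -100 bp held 641 regions and that from 100 to 200 bp held 130.

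**Figure D2:**
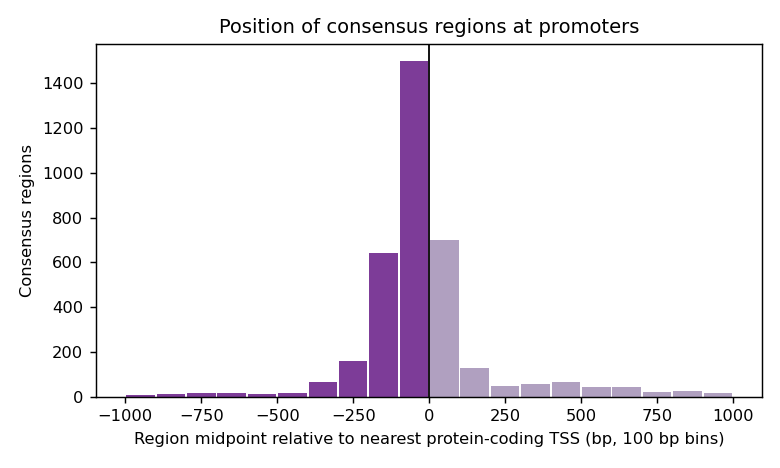
Number of consensus regions (y axis) by the distance of their midpoint from the nearest protein-coding TSS (x axis, bp, bins of 100 bp, negative values upstream; dark bars upstream, light bars downstream). The 100 bp upstream of the TSS held 1500 regions and the 100 bp downstream 698.

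The promoters with the steadiest high signal were chosen by their lowest value over the 9 libraries, given as CPM, counts scaled to a common total of reads in the windows. TLE4, a transcriptional corepressor of the Groucho family, had 231 ± 22.7 CPM (SD, n = 3 biological replicates) in its window at chromosome 9, 79571574 to 79571973 (hg38, ENSG00000106829.18). This was 22.1 times the median of 10.5 CPM over 7820 protein-coding windows without a peak. DESI2 (chromosome 1, 244652736 to 244653135) had 221 ± 27.7 CPM, and PCDH9, a protocadherin (chromosome 13, 67230246 to 67230645), had 195 ± 14.2 CPM. The window of ENSG00000149930.17 (chromosome 16, 29973442 to 29973841), to which position gave only the name of an uncharacterised gene, LOC124903762, had 188 ± 9.93 CPM. B3GALNT2, a glycosyltransferase, had 181 ± 4.86 CPM, and GUK1, guanylate kinase, 179 ± 7.58 CPM. EMD, which encodes the nuclear envelope protein emerin, had 178 ± 12.1 CPM on the X chromosome, and ADSS2, an enzyme of AMP synthesis, had 176 ± 14.2 CPM. MAZ, a zinc finger factor that binds guanine-rich promoter sequences, had 160 ± 12.1 CPM (chromosome 16, 29805907 to 29806306).

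The remaining promoters of these 20 ranged from 139 to 169 CPM. RRM2B, a p53-inducible ribonucleotide reductase subunit, had 165 ± 16.6 CPM, and GADD45A, a growth arrest and DNA damage inducible gene, had 154 ± 5.86 CPM. PKNOX1, a homeobox factor, had 169 ± 22.5 CPM, TSPAN17, a tetraspanin, 164 ± 12.4 CPM, and IBA57, an iron-sulfur cluster assembly factor, 164 ± 8.19 CPM. SDE2 had 149 ± 12 CPM and ARF1, a GTPase of Golgi traffic, 141 ± 8.90 CPM. DOP1B had 140 ± 4.39 CPM, BORA, an activator of Aurora A kinase, 139 ± 8.74 CPM and the window named by position for CHKB, choline kinase beta (ENSG00000254413.8), 139 ± 9.78 CPM. Of the 20 promoters, 8 lay on chromosome 1 beyond 200 Mb. Windows in this segment that had no peak and were not named for a protein-coding gene averaged 12.1 ± 0.429 CPM (n = 3), against 8.65 ± 0.460 CPM over the other autosomal windows of this kind.

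Windows with a consensus peak had 6.27 ± 0.415 (SD, n = 3) times the mean read density of all other windows. The ratio was 5.85 in BioRep1, 6.28 in BioRep2 and 6.68 in BioRep3. Within protein-coding windows alone it was 3.58 ± 0.157. The median over protein-coding windows with a consensus peak was 64.7 ± 3.29 CPM, against 10.7 ± 0.440 CPM for those without any peak. Peaks and densities come from the same reads, so the ratio describes the peak lists and is not an independent test of them. Mitochondrial reads made up between 2.34 and 4.32% of the reads in windows. Without the mitochondrial windows the ratios were 5.37, 5.91 and 6.30.

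Promoters that are textbook examples of G-quadruplex formation did not differ past the threshold from other protein-coding promoters in how often they had a consensus peak. Of the 15 genes on this list 13 had a named window and 2 of these had a consensus peak (15.4%, 4.33 to 42.2%), against 25.4% of other genes (Fisher's exact test, two-sided, adjusted p = 0.562). Without BioRep1 the share was 30.8%, against 35% of other genes, and with a peak in any replicate it was 53.8%, against 43.2%; neither passed. HIF1A, the oxygen-regulated transcription factor, had 86.3 ± 9.09 CPM (SD, n = 3; chromosome 14, 61695314 to 61695713), with a peak in all 3 replicates. Peaks were present in 2 replicates at VEGFA, a growth factor for blood vessels, with 42.9 ± 1.48 CPM, and at KIT, a receptor tyrosine kinase, with 41.8 ± 7.67 CPM. Peaks were present in 1 replicate at MYB (37.5 ± 4.26 CPM), RB1 (33.9 ± 3.57 CPM) and BCL2 (25.8 ± 5.79 CPM). None of the 3 lists had a peak in the windows of RET (27.4 ± 5.01 CPM), MYC (21.8 ± 1.03 CPM), TERT (14.2 ± 0.314 CPM), PDGFRB (8.48 ± 4.27 CPM) or SRC (8.22 ± 2.47 CPM). The MYC window, at chromosome 8, 127735235 to 127735634, thus had 2.08 times the median of protein-coding windows without a peak. A window covers 400 bp around 1 annotated TSS, the outermost one, and leaves out structures elsewhere in a promoter. The sequence that made MYC or another of these genes a textbook case may lie outside its window. Its position was not checked here, so a window without a peak does not show that this sequence had none.

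**Figure D3:**
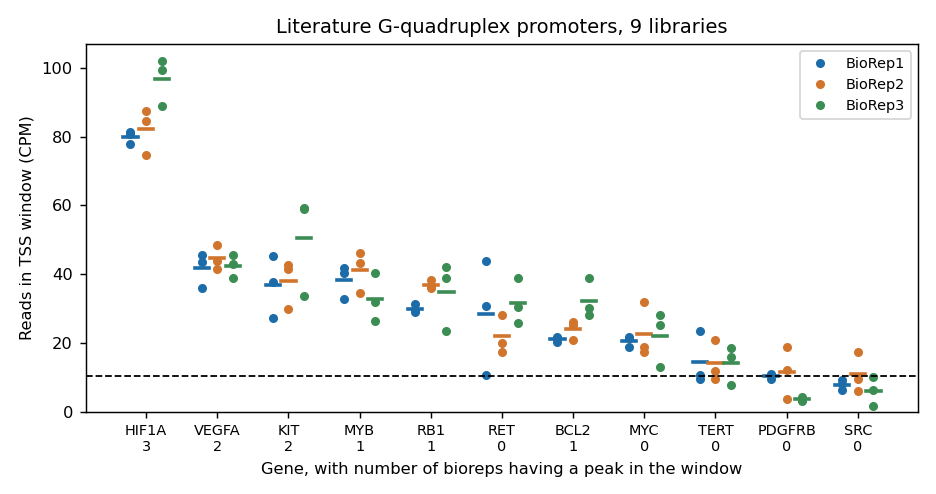
Reads in the TSS window (y axis, CPM) of textbook G-quadruplex promoters (x axis, with the number of biological replicates that had a peak in the window). Points are the 9 libraries, coloured by biological replicate, short bars are the mean of 3 technical libraries, and the dashed line is the median of 10.5 CPM over protein-coding windows without a peak. HIF1A, with a peak in all 3 replicates, averaged 86.3 CPM and MYC, without a peak in its window, 21.8 CPM.

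Genes of DNA replication, chromatin regulation, chaperones, cytosolic ribosomes and the respiratory chain carried consensus peaks more often than other protein-coding genes. Of 22 lists fixed before the data were examined, 5 had a higher share, 3 a lower share, and 14 did not pass an adjusted p of 0.05 (Fisher's exact test, two-sided, Benjamini-Hochberg over the lists). DNA replication genes had one in 14 of 22 windows (63.6%, 43.0 to 80.3%; adjusted p = 0.000743). POLD1, the catalytic subunit of DNA polymerase delta, had 102 ± 18.9 CPM (n = 3) and POLE, that of polymerase epsilon, 81.6 ± 6.23 CPM. ORC6 and PRIM1 had peaks in 2 replicates, with 49.0 ± 5.90 and 48.9 ± 3.03 CPM. The list named chromatin remodellers holds chromatin regulators of other kinds as well. It had a consensus peak in 12 of 21 windows (57.1%, 36.6 to 75.5%, adjusted p = 0.00705). Among them were the histone deacetylase HDAC1 with 121 ± 4.93 CPM and the insulator protein CTCF with 92.0 ± 16.0 CPM. KDM1A had a peak in 2 replicates with 57.6 ± 7.64 CPM.

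Heat shock proteins and chaperones had a consensus peak in 10 of 18 windows (55.6%, 33.7 to 75.4%; adjusted p = 0.0190). DNAJC3, a co-chaperone of the endoplasmic reticulum, had 92.1 ± 9.04 CPM (n = 3) and CCT6A, a chaperonin subunit, 91.3 ± 14.4 CPM, while DNAJA1 and HSPH1, with peaks in 2 replicates, had 55.2 ± 8.80 and 51.2 ± 7.98 CPM. Cytosolic ribosomal protein genes had one in 27 of 51 windows (52.9%, 39.5 to 66.0%; adjusted p = 0.000158). RPS2, among those with one, had 98 ± 3.53 CPM. RPS13 (62.0 ± 15.8 CPM) and RPS6 (56.3 ± 5.53 CPM) had peaks in BioRep2 and BioRep3 alone. Nuclear genes of the respiratory chain had one in 23 of 56 windows (41.1%, 29.2 to 54.1%; adjusted p = 0.0350), and in 71.4%, against 34.8% of other genes, without BioRep1. COX5A, a cytochrome oxidase subunit, had 118 ± 15 CPM and ATP5PD, an ATP synthase subunit, 109 ± 9.81 CPM. ATP5ME had 71.8 ± 17.6 CPM and ATP5PO 62.7 ± 7.05 CPM, with peaks in 2 replicates. The call for the respiratory chain was lost when windows were named within 1 kb (33.3%, adjusted p = 0.127, with a range of 8.45e-08 to 0.127 over 8 alternatives).

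Olfactory receptors, keratins and S-phase histones carried consensus peaks less often than other protein-coding genes. None of 351 olfactory receptor windows had a consensus peak (upper limit 1.08%; adjusted p = 1.82e-44), and none of 132 keratin and keratin-associated protein windows had one (upper limit 2.83%; adjusted p = 2.47e-16). OR6V1 and OR2V1, the olfactory receptors with the most reads, had 14.4 ± 4.84 and 13.7 ± 2.58 CPM (n = 3). The windows of KRT18 and KRT8, keratins of simple epithelia, had 18.6 ± 1.82 and 14.7 ± 5.40 CPM. The KRT8 window (chromosome 12, 52949755 to 52950154) lies close to that of KRT18 (52948672 to 52949071). It may not be the main promoter of KRT8. The S-phase histone genes had a consensus peak in 0 of 63 windows (upper limit 5.75%; adjusted p = 1.01e-07). H2AC25 and H1-4, with 62.7 ± 1.17 and 51.5 ± 4.38 CPM, had peaks in BioRep2 and BioRep3 but not in BioRep1. Counting peaks in at least 2 replicates raised the histone share to 7.94%, against 36.3% of other genes.

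Proteasome genes had a consensus peak in 10 of 26 windows (38.5%, adjusted p = 0.253). PSMD8 (80.3 ± 12.3 CPM, n = 3) and PSMA5 (79.4 ± 14.4 CPM) had one, and PSMD9 (65.7 ± 11.5 CPM) and PSMD3 (49.7 ± 5.41 CPM) had peaks in 2 replicates. With a peak in at least 2 replicates the proteasome share was 69.2% and passed (adjusted p = 0.00207, with a range of 0.000887 to 0.340 over 8 alternatives). Without BioRep1 it was 65.4%, against 34.9% of other genes, and passed as well (Fisher's exact test, adjusted p = 0.00452). Helicases and other G-quadruplex binding factors had one in 5 of 12 windows (41.7%, adjusted p = 0.268; 0.0168 against all named genes, range 0.0168 to 0.434; share without BioRep1 66.7%), among them MAZ and BLM, the Bloom syndrome helicase (80.6 ± 4.67 CPM). SP1 (68.1 ± 7.55 CPM) and BRIP1 (44.4 ± 2.14 CPM) had peaks in 2 replicates. Glycolysis genes had one in 3 of 8 windows (37.5%, adjusted p = 0.494), with 85.8 ± 12.8 CPM at PGAM1 and 57.2 ± 7.33 CPM at LDHA. ALDOA (36.2 ± 8.74 CPM) and PFKL (35.7 ± 3.78 CPM) had a peak in BioRep3 alone.

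Tumour suppressors had a consensus peak in 6 of 17 windows (35.3%, adjusted p = 0.491; 0.0168 against all named genes, range 0.0168 to 0.581), among them NF2 with 133 ± 21.5 CPM and FBXW7, a ubiquitin ligase subunit, with 75.8 ± 10.9 CPM (n = 3). The window of BRCA1 (chromosome 17, 43170046 to 43170445) had a peak in 2 replicates, with 43.9 ± 3.58 CPM. It lies at the outermost annotated TSS and may not be the main promoter of the gene. CDKN2A had a peak in 1 replicate, with 41.9 ± 2.31 CPM. Proto-oncogenes had one in 7 of 30 windows (23.3%, against 25.4% of other genes; adjusted p = 1), and in 40.0%, against 35%, without BioRep1, where the list did not pass either. The highest were CCNE1, cyclin E1, with 115 ± 11.3 CPM and AKT2, a kinase of insulin signalling, with 88.2 ± 4.70 CPM. BRAF (57.9 ± 0.928 CPM) and MDM2 (56.2 ± 12.7 CPM) had peaks in 2 replicates. This list shares 8 of its windows with the textbook G-quadruplex list. ZNF genes had one in 71 of 342 windows (20.8%, against 25.5% of other genes; adjusted p = 0.102), and in 36.8%, against 34.9%, without BioRep1. ZNF7 had 144 ± 27.9 CPM and ZNF862 119 ± 11.7 CPM, and ZNF584 (71.9 ± 12.3 CPM) and ZNF337 (70.0 ± 13.2 CPM) had peaks in 2 replicates. HOX genes had one in 4 of 23 windows (17.4%, adjusted p = 0.525; 30.4% without BioRep1), among them HOXC13 (77.6 ± 3.56 CPM). HOXA5 (43.9 ± 6.70 CPM) and HOXA10 (43.5 ± 6.33 CPM) had peaks in 2 replicates.

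Markers of differentiated tissues had no consensus peak in any named window. This held for 14 kidney tubule and podocyte markers (adjusted p = 0.0681), 13 blood cell markers (0.102), 11 liver markers (0.130), 11 muscle markers (0.130), 9 neuronal markers (0.194) and 5 fibroblast markers (0.439). None of these lists passed, and their upper limits ran from 21.5 to 43.5%. Counting peaks in at least 2 replicates, kidney (adjusted p = 0.00740, range 0.00142 to 0.509 over 8 alternatives), liver (0.0180, range 0.0180 to 0.686) and muscle markers (0.0180, range 0.00724 to 0.686) were lower than other genes, and without BioRep1 the adjusted p was 0.00770, 0.0198 and 0.0198. Blood cell markers passed as lower with a peak in any replicate (7.69%, adjusted p = 0.0179, range 0.0179 to 0.509). With peaks in at least 2 replicates, neuronal markers had 22.2% (adjusted p = 0.614), against 36.2% of other genes. Blood cell markers then had 7.69% (adjusted p = 0.0632), and neither list passed, also without BioRep1. Kidney markers were highest at LRP2, the tubular receptor megalin, with 21.5 ± 2.93 CPM (n = 3) and at WT1 with 20.2 ± 3.42 CPM. SYP (40.2 ± 1.75 CPM) and MAP2 (40.0 ± 5.65 CPM), neuronal markers, and CD8A (34.1 ± 2.74 CPM), a T cell marker, had peaks in 2 replicates. The window named by position for TF, transferrin (chromosome 3, 133661799 to 133662198, ENSG00000242337.5), had a peak in BioRep3 alone (29.8 ± 5.36 CPM). It may not be the main promoter of this gene. TTR (16.2 ± 4.36 CPM), CD79A (11.4 ± 3.07 CPM) and MYOG (15.5 ± 3.51 CPM) had no peak. The same held for ACTA1 (14.6 ± 0.808 CPM), COL1A1 (10.7 ± 1.67 CPM) and THY1 (10.2 ± 2.64 CPM).

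**Figure D4:**
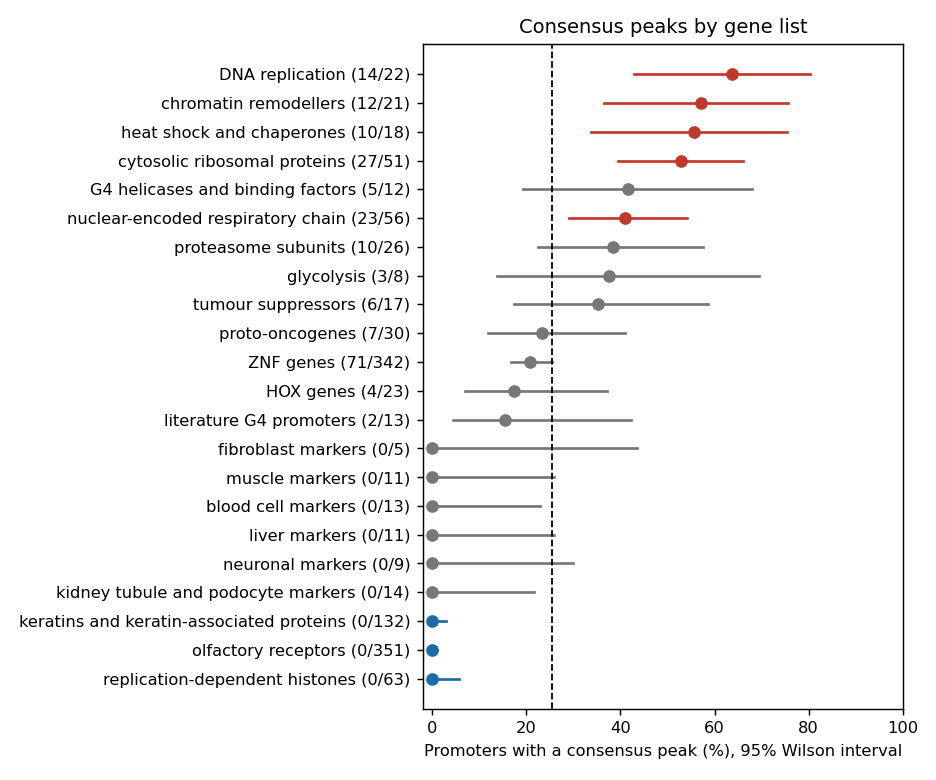
Share of promoters with a consensus peak (x axis, %) in 22 gene lists, with the numbers of promoters in parentheses. Points are shares with 95% Wilson intervals, red for lists above and blue for lists below other protein-coding genes at an adjusted p under 0.05, grey for the rest, and the dashed line is 25.4%, the share of all protein-coding windows. DNA replication genes reached 63.6% and olfactory receptors 0 of 351.

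Read density needs no peak call and was tested for the same lists. Relative to the median of protein-coding windows, the median log2 density was higher by 1.22 ± 0.22 (SD, n = 3) for chaperones, 1.13 ± 0.10 for DNA replication and 1.02 ± 0.09 for chromatin remodellers. It was higher by 0.95 ± 0.12 for ribosomal proteins, 0.95 ± 0.11 for the respiratory chain, 0.81 ± 0.13 for the proteasome and 0.29 ± 0.05 for ZNF genes. Olfactory receptors stood at -2.02 ± 0.16, keratins at -1.84 ± 0.11, blood cell markers at -1.77 ± 0.37, liver markers at -1.47 ± 0.15 and kidney markers at -1.34 ± 0.17. These 7 higher and 5 lower lists passed against 10000 random lists of the same size (permutation test, adjusted p from 0.0011 to 0.0477), and 10 of 22 lists did not. The lists that did not pass were fibroblast (-1.65), muscle (-1.15), neuronal (-0.47) and histone genes (-0.21 ± 0.17), the textbook G-quadruplex promoters (0.20 ± 0.18), HOX (0.28), proto-oncogene (0.37), tumour suppressor (0.52), glycolysis (0.54) and G-quadruplex factor genes (0.79). ZNF genes thus lay above the median in density and below other genes in their share of peaks, where the list did not pass, and S-phase histones, with 0 consensus peaks, did not pass in density. Without BioRep2 the calls for ZNF, kidney and liver genes were lost and 9 lists passed, without BioRep3 those for proteasome, ZNF and liver genes were lost and 9 passed, and with at least 10 reads per window those for proteasome and ZNF genes were lost and 10 passed (adjusted permutation p of the lost calls 0.0528 to 0.139). Genes are not independent replicates, and the random lists describe these libraries only. No input was used, so differences in how uniquely reads map, in copy number and in tagmentation remain in these densities. Their part in the lower lists was not tested.

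No TSS window was called different between the biological replicates in the main test. Among 17499 windows with enough reads, edgeR's quasi-likelihood test called 0 windows at an adjusted p under 0.05 over the 3 replicates, with 1379 at an unadjusted p under 0.05. DESeq2 called 0, with 334 at an unadjusted p under 0.05. BioRep2 against BioRep1 gave 0 windows (1328 unadjusted; DESeq2 0 and 442), BioRep3 against BioRep1 gave 0 (1508; DESeq2 0 and 551), and BioRep3 against BioRep2 gave 0 (979; DESeq2 0 and 248). The smallest adjusted p with edgeR was 0.0593, for BioRep3 against BioRep1. Each of the DESeq2 counts at an unadjusted p under 0.05 was below the share of 0.05 that chance alone gives. The DESeq2 p-values were thus conservative here, and its 0 calls add little to those of edgeR. In each of the 21 gene lists with a tested window, 0 windows were called when adjusted over the list alone. In simulated data the same fit called 19.4% of windows changed 1.5-fold, 62.7% of those changed 2-fold and 84.8% of those changed 3-fold. Without the filter on low counts, 25 windows were called over the 3 replicates, 6 for BioRep2 against BioRep1 and 28 for BioRep3 against BioRep1, and 9, 6 and 3 of these were mitochondrial. Of the 28, 23 were higher in BioRep3. With the technical number as a block, 1 window was called for BioRep2 against BioRep1 (TMEM9) and 1 for BioRep3 against BioRep1 (DCAF4). Leaving out replicate 1 of BioRep1, any library of BioRep2 or replicate 2 of BioRep3 gave 1 or 2 calls in at least 1 of the comparisons, at ETFDH, C4orf46, DCAF4 or TMEM9, named after their values were seen.

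Libraries of the same biological replicate were slightly more alike than libraries of different ones. The mean Pearson correlation of log2 CPM across windows was 0.860 for 9 pairs within replicates and 0.853 for 27 pairs between them. The difference of 0.00685 had p = 0.00357 in an exact one-sided permutation test, the smallest value that 280 splits allow. Leaving out any library of BioRep2 or BioRep3 ended the call, with differences from 0.00188 to 0.00469 and exact p from 0.207 to 0.314. Leaving out a library of BioRep1 kept p at 0.00357. Counts differed by less than sampling noise in all 9 pairs of technical libraries (chi-square per degree of freedom 0.866 to 0.921) and in all 9 pairs of BioRep2 with BioRep3 (0.921 to 0.967), while pairs of BioRep1 with either lay at about sampling noise (0.973 to 1.03). By the labels, the 3 technical libraries counted as 1 replicate in every mean and SD.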

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

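The test without mitochondrial windows, the comparison of read ratios at lower depth, the bound on the highest thinned draw and the counts over other splits of the libraries were chosen only after the results were seen, and the remaining tests were fixed beforehand.

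The ratio of read density between windows with a consensus peak and all other nuclear windows was 5.37 in BioRep1, 5.91 in BioRep2 and 6.30 in BioRep3, a largest difference of 0.930 (exact permutation p = 0.00357 over 280 splits of 9 libraries), and BioRep1 had the fewest peaks, 7931 against 13049 in BioRep3. A larger mitochondrial share in BioRep1 is argued against for this read ratio only. The ratio leaves out mitochondrial windows by its construction, and that p of 0.00357 belongs to it. A part of the mitochondrial share in the peak numbers was not tested. Lower depth is argued against for the read ratio, since the 3 libraries of BioRep2 and BioRep3 with fewer reads in windows than the deepest BioRep1 library had ratios of at least 5.90, above 5.45, the highest in BioRep1, by more than the largest technical SD of 0.123. With all libraries thinned to the same background, BioRep1 had 0.846 times the windows of BioRep3 past a Poisson threshold (0.842 before thinning), and the highest of 20 draws, 0.852, stayed under the 0.95 that depth as the whole cause required, although the draws reached past the lower bound of 0.85 set beforehand. A part played by depth in the deposited peak numbers, where BioRep1 had 0.608 times those of BioRep3, stays open, and no biological explanation was tested, since the labels give the replicates no condition.

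Replicate 2 of BioRep1, the shallowest library, stood apart from the other 8 in 2 of 37 measures, where chance alone separates about 1 in 20. It had 9.97% of windows without reads, the next library 7.33%. Its mitochondrial share was 4.32%, the next 3.25%. Its mitochondrial reads, 16054, were the fewest of the 9 libraries, so the high share came from its low total of 372030 reads in windows. A count of 2 of 37 measures is also close to the rate given for chance.

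Mitochondrial reads changed less between libraries than all reads, 1.23-fold against 2.27-fold from the lowest to the highest library. A candidate explanation is duplicate removal, which limits the reads a position can hold. In that case the counts of mitochondrial windows should vary by less than sampling noise, and their chi-square per degree of freedom was 0.179, under the bound of 0.7, against 0.986 for nuclear windows without a peak. Nuclear windows with 500 or more reads stood at 0.841. A true difference in mitochondrial DNA between cultures was not tested.

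The promoters with the steadiest high CPM lay together on the distal part of chromosome 1, where 8 of 20 were found and 0.486 were expected from the number of promoters with a consensus peak. A higher local background, as extra copies of the segment could give, is a candidate explanation. Windows of the segment without a peak had 1.40 ± 0.03 times the background of other autosomal windows (SD, n = 3), and after division by local background 0 of the top 20 lay there. The median of its promoters with a consensus peak was 1.27 ± 0.02 times that elsewhere, while its share of promoters with one, 29.4% against 26%, did not differ past the threshold (Fisher's exact p = 0.220). Copy number itself was not measured here, the higher background had been seen before this test, and 6 of the 20 promoters were shared before and after the division. The local background of the 20 promoters after division ran from 1.09 CPM at NIPA2 to 11.6 CPM at TLE4. The segment averaged 12.1 CPM. Division by low values can by itself move promoters above those of the segment. The count of 0 of 20 therefore does not decide for a higher background as the cause.

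Whether chance can be excluded for the edgeR counts at an unadjusted p under 0.05 was checked by splitting the libraries in other ways. Over the 3 replicates, 1 of 100 splits, the real one, gave as many as 1379 windows, and the highest other gave 1254, so chance is argued against for this count. Each pairwise comparison allows only 10 splits, too few for a share under 0.05. In fits to each pair of replicates alone, which give other counts than the contrasts of the fit to all libraries, the real split gave 1137 windows for BioRep2 against BioRep1 (highest other 685), 1293 for BioRep3 against BioRep1 (673) and 861 for BioRep3 against BioRep2 (671), each the only 1 of its 10 to reach that number.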

How the results depend on the processing

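The settings without mitochondrial windows, with thinned libraries, with names within 1 kb and for the position relative to the TSS were chosen after seeing the data. Of 144 recomputed values for the main results, 99 kept their side of the threshold or stayed within the spread or 1.5 times the count, 13 gained and 12 lost a call, and 20 without a test moved by more. Of 176 for single gene lists, 143 kept direction and side, 17 gained and 1 lost a call, and 15 reversed.

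Calls between replicates by edgeR were 0 with other size factors, with library totals and without mitochondrial windows. The library totals were those of the tested windows, so each of these settings can scale away a difference shared by most tested windows. DESeq2 gave 0 as well, but with fewer unadjusted p-values under 0.05 than chance alone gives. Without the filter the edgeR calls were 25 over the 3 replicates, 6 for BioRep2 against BioRep1 and 28 for BioRep3 against BioRep1. Of these 28, 23 were higher in BioRep3. More windows were tested then, 56196. With the technical number as a replicate block, 1 window was called for BioRep2 against BioRep1 (TMEM9) and 1 for BioRep3 against BioRep1 (DCAF4), and the block changed no other call. Libraries of the same number did not deviate together (r from -0.0124 to 0.0251), so the number does not pair them. Leaving out a library gave 0 to 1 windows over the 3 replicates, 0 to 1 for BioRep2 against BioRep1 and 0 to 2 for BioRep3 against BioRep1. The windows were ETFDH and C4orf46 without replicate 1 of BioRep1, ETFDH and DCAF4 without any 1 library of BioRep2, TMEM9 without replicate 2 of BioRep2 and DCAF4 without replicate 2 of BioRep3, named after their values were seen. The cause was not tested.

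The gain in correlation within replicates, 0.00685, ranged from 0.00188 to 0.0183 without single libraries and from 0.00145 to 0.00996 when these were also thinned to the same total of reads in windows. It was 0.0024 over all windows with any read and 0.00405 over windows without any peak (exact permutation p = 0.00357 for each). It lost its call without any 1 library of BioRep2 or BioRep3 (exact p 0.207 to 0.314, thinned 0.0607 to 0.25). The thinned values without replicates 1, 2 and 3 were 0.00479, 0.00362 and 0.00349 for BioRep2 and 0.00145, 0.00185 and 0.00237 for BioRep3. The mean share of peaks in all lists moved from 62.2% to 30.9% with 50% reciprocal overlap and to 84.7% with a peak in 1 other list. Windows with a consensus peak numbered 3073 with peaks wider than the median of their list. Regions at a TSS moved from 70.6% to 71.7%, 74.7% and 66.5% with reciprocal overlap, wider peaks and peaks in 2 replicates, and lay between 67.1 and 69.2% without single replicates. Regions within 1 kb of a TSS were 81.4%, against 62.7% within 200 bp, 77.6% and 75.2% for the own peaks of BioRep2 and BioRep3, and 79.4 to 81.3% without single replicates. The density ratio of 6.27 moved to 3.58 in protein-coding windows and to 7.65 with medians. The share upstream moved from 68.3% to 71.0% with close RefSeq 5′ ends and to 62.9%, 62.0% and 60.8% for the own peaks of BioRep1, BioRep2 and BioRep3. Counting peaks of any replicate made 13 lists pass in place of 8. The read density of 12 lists passed, against 9 to 12 without single replicates and 10 with at least 10 reads per window. The lists that turned from below to above other genes passed in neither case, apart from ZNF genes against all named genes (20.7%, adjusted p = 3.2e-06, with a range of 3.2e-06 to 0.659 over 8 alternatives). Against that background, whose share is 11.4 to 11.5% by its construction with non-coding windows, textbook promoters (15.4%), proto-oncogenes (23.3%) and HOX genes (17.4%) turned too. With peaks in at least 2 replicates proto-oncogenes (46.7%) and ZNF genes (37.7%) turned, and with peaks in any replicate textbook promoters (53.8%), proto-oncogenes (60.0%), HOX genes (43.5%) and ZNF genes (48.8%). Proto-oncogenes turned with names within 1 kb (26.5%) and without each replicate (26.7 to 40.0%), and ZNF genes without BioRep1 (36.8%; 21.1 to 36.8% without single replicates). The cause was not tested for these. The GC corrections and the motif search were not run.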

Other observations

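The families, whose filter was revised once after a first grouping, the position relative to the TSS and the comparison of autosomal segments with X were chosen only after the results were seen; the relation of background to peaks and the background on X were predicted beforehand.

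Nuclear protein-coding genes were also grouped by the letters that open their symbols. Such families can join unrelated genes, and OR, KRT, ZNF, RPS and RPL overlap the fixed lists. Of 61 families with at least 20 promoters, 11 had a higher and 10 a lower share with a consensus peak than other genes (Fisher's exact test, adjusted p under 0.05). Translation initiation factors (EIF) had one in 24 of 36 promoters (66.7%, 50.3 to 79.8%; adjusted p = 7.47e-06), among them EIF1 with 101 ± 7.45 CPM (SD, n = 3) and EIF2B4 with 94.3 ± 13.3 CPM. Centrosomal proteins (CEP) had one in 21 of 31 (67.7%, 50.1 to 81.4%; adjusted p = 1.91e-05), with 129 ± 12.3 CPM at CEP131 and 104 ± 18.5 CPM at CEP43. Protein phosphatase subunits (PPP) had one in 26 of 51 (51.0%, adjusted p = 0.00115), with 82.7 ± 6.84 CPM at PPP4R3A and 81.8 ± 5.35 CPM at PPP2R5A. Genes with CDC symbols had one in 14 of 26 (53.8%, adjusted p = 0.0130). Among them were CDC42BPA with 120 ± 8.50 CPM and CDC25A, a phosphatase that drives S-phase entry, with 84.6 ± 7.93 CPM. DEAD-box helicases (DDX, 12 of 24, adjusted p = 0.0337), kinesins (KIF, 14 of 29, adjusted p = 0.0337) and RAB GTPases (22 of 53, adjusted p = 0.0368) were also higher, with 101 ± 13.9 CPM at DDX59, 85.6 ± 5.68 CPM at KIF20B and 133 ± 14 CPM at RAB40B.

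Beta-defensins, taste receptors, serine proteases, and genes with CD and IL symbols were among the lower families. Beta-defensins (DEFB) had a consensus peak in 0 of 32 promoters (upper limit 10.7%; adjusted p = 0.00115), taste receptors (TAS) in 0 of 24 (upper limit 13.8%; adjusted p = 0.0101) and serine proteases (PRSS) in 0 of 20 (upper limit 16.1%; adjusted p = 0.0182). ZNF genes, grouped by symbol and not by the fixed list, were lower as well, with one in 74 of 369 (20.1%, 16.3 to 24.4%; adjusted p = 0.0445), while the fixed list did not pass (20.8%, adjusted p = 0.102), lay above other genes without BioRep1 (36.8% against 34.9%), turned above the background against all named genes (adjusted p = 3.2e-06, range 3.2e-06 to 0.659) and had a higher read density than other genes (log2 0.29, adjusted p = 0.0477). Genes with CD symbols had one in 4 of 69 (5.80%, 2.28 to 14%; adjusted p = 0.000471). They were CD2BP2, a splicing factor subunit (93.5 ± 4.19 CPM, SD, n = 3), CD99L2 (85.6 ± 6.79 CPM), and the complement regulators CD46 (73.8 ± 13.3 CPM) and CD59 (49.1 ± 7.43 CPM). Interleukin and receptor genes (IL) had one in 4 of 57 (7.02%, adjusted p = 0.00485), at the windows named for IL6ST, IL17RA, IL13RA1 and IL5. The IL5 window (chromosome 5, 132556639 to 132557038) lies at the outermost annotated TSS. It may not be the main promoter of IL5, so its peak may belong to a neighbouring gene.

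Segments of 5 Mb differed in background and in the share of promoters with a consensus peak. A hypothesis was that local background, set by copy number or base composition, may raise the calls. Across 225 autosomal segments with at least 20 promoters, Spearman's rho between background and share was 0.412 and Pearson's r 0.438 (permutation p = 1e-05 each, the smallest value that 100000 permutations give). Without the 2 segments farthest from the median background r was 0.424. The values go with the hypothesis but do not decide for it. Background and calls come from the same reads, so any influence on both would give such a relation. Base composition could not be separated from copy number here. Segments of 1 genome are not independent replicates.

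Fewer promoters had a consensus peak on the X chromosome than on autosomes, 73 of 655 (11.1%) against 3410 of 13065 (26.1%; Fisher's exact p = 1.92e-20). A lower background on X might lower the share, but it was 0.901 ± 0.00974 (SD, n = 3) times the autosomal level, within its spread of the bound of 0.9 set beforehand for excluding this, so that value alone leaves it open. Autosomal segments with a background no higher than that of X had a consensus peak at 18.1% of promoters (16.7 to 19.5%), above the 8.96 to 13.8% interval of X, which argues against background as the whole cause. Differences in gene content were not tested.

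The upstream position of the region midpoints might come from promoters shared with a gene on the opposite strand. Without every TSS that had an opposite-strand TSS within 1000 bp, 68.4% (66.5 to 70.3%) of 2348 regions still had their midpoint upstream, which argues against this explanation. Outermost TSSs lie upstream of other TSSs of the gene and would tend to move regions the other way. The motif content of these regions was not analysed here.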
